A study of Homo sapiens with 10 samples.

How the data were processed

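PolyA-selected RNA of HUVECs was sequenced as paired reads in 10 libraries, and each library is placed in its group by its title and by the treatment recorded for it: 5 with the non-specific mimic and 5 with the miR-375 mimic, both at 50 nM for 48 h. The treatment protocol text names the miR-375 mimic for every sample. The title, description and treatment characteristic of each sample separate the groups, and these were followed.

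The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2, and the genome builds GRCh38 and GRCm38 with no role for either. Gene identifiers in the table are human Ensembl identifiers. One deposited table holds, per the file headers, 10 library columns, a log2 fold change, a p-value and an adjusted p-value per gene. The library values are a signal in the sense that the authors deposited gene counts divided by one size factor per library; the tool that made the size factors and the test behind the deposited p-values are not given in the sources used here. The form of the values was read from the table itself. In 9 columns 100% of values lay within 0.01 of a whole multiple of one step, so that whole reads were recovered for these libraries. For miR-375 mimic replicate 1 the step lay so close to 1 that it could not be told from rounding, and count tests left that library out. No read total is given for it. The totals cover the listed genes only, and the smallest mean value in the table is 9.50, so genes of lower level were not analysed here. The deposited log2 fold change and p-values, the authors' own comparison, were used only as an alternative and where named. All value columns were matched to samples (0 were not).

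Of the 15551 identifiers, 15506 matched the GENCODE release 29 annotation (GRCh38), which gave coordinates, gene types and 3' UTRs; the annotation release used by the authors is not given in the sources used here. The table had turned 22 symbols into dates and left 28 blank, and these were restored from the identifier where it matched.

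The values were analysed as log2(value + 1) with limma 3.58.1 (R 4.3.3), with a trend of variance on expression, one factor for the group and Benjamini-Hochberg adjustment over all genes; adjusted p under 0.05 was called. The filter on a mean of at least 1 removed 0 genes. Scaling by other factors moved the median log2 fold change of all genes by less than 0.1. Of the 98 genes named, all but 3 follow a rule set before the data were examined: KLF5; the 10 largest changes in each direction among called genes with a mean of at least 10 and groups that do not overlap, leaving out clone and locus names; up to 4 members of each gene list by smallest adjusted p; and the other KLF genes with a mean of at least 10. The ranking by log2 fold change uses the pseudocount of 1. Not every gene that the rule picks is reported. PCDHB5, PCDHB14 and PCDHA10 were chosen after their values were seen.

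In all, 29 gene lists were written from general knowledge before the data were examined: reported miR-375 targets, the KLF family, NF-kB and adhesion, angiogenic receptors and ligands, Notch, endothelial identity, flow-responsive and anticoagulant genes, mitosis, DNA replication, p53 targets, interferon response, cholesterol and lipid synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress, YAP/TEAD targets, mesenchymal transition and TGF-beta, extracellular matrix, autophagy and lysosome, oxidative phosphorylation, the small-RNA pathway, 6 lists of cell type markers and 3 quality lists (mitochondrially encoded, immediate early and ribosomal protein genes). The 27 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. With the correlation estimated from the data, the calls of the reported targets and of cholesterol synthesis held and the other 6 calls did not.

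Seed matches were searched with the sequence of miR-375-3p (UUUGUUCGUUCGGCUCGCGUGA) in the longest annotated 3' UTR of 13060 genes: CGAACAAA (8mer), CGAACAA (7mer-m8), GAACAAA (7mer-A1) and GAACAA (6mer). Medians of log2 fold changes were compared by a two-sided permutation test over genes with 100000 resamples, and with 2000 resamples for most alternatives, whose smallest p is 0.0005. The intervals given for medians are 95% bootstrap intervals.

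On simulated values made from the means and spread of these 15551 genes, with 50 genes changed at each of 4 folds, limma recovered 38% of genes changed 1.25-fold, 74% at 1.5-fold, 90% at 2-fold and 92% at 4-fold, with 5 false calls of 152. Only 200 genes were changed there, against 8549 called in the data, so the adjusted threshold was stricter and these rates do not carry over directly. A planted shift of the Notch list was recovered, with 0 of the other lists called. Within groups, the 9 libraries with recovered reads differed by more than sampling noise (chi-square per degree of freedom of 3.60 to 19.2), so none of these was a copy or a second sequencing of another; libraries made from the same RNA are not ruled out. Alternatives were other pseudocounts and filters, the replicate number as a block, leaving out each library, other scaling factors, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of 9 libraries, the deposited comparison, and other set tests and site classes. The recovered reads gave 8463 called genes with edgeR and 8414 with DESeq2. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.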

Results

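Gene expression was measured by polyA RNA-seq in human umbilical vein endothelial cells (HUVECs), primary cells that line the vein of the umbilical cord. The cells had received 50 nM of a synthetic microRNA mimic for 48 h. In 5 libraries the mimic was a non-specific one (NS mimic), and in the other 5 it carried the sequence of miR-375, a microRNA best known from pancreatic islets. The series names repression of KLF5 by miR-375 and angiogenesis in diabetic limb ischemia as its subject, so the comparison asks which endothelial transcripts differ when miR-375 is supplied. The deposited table lists 15551 genes. In the 9 libraries whose reads could be recovered, 34.6 M to 53.9 M reads fell in these genes (36.3 M to 53.9 M in 5 libraries with the NS mimic and 34.6 M to 47.4 M in 4 with the miR-375 mimic). Values are normalized read counts, given as mean ± SD over 5 libraries per group. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical. Levels of the mimic itself were not analysed here.

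The transcriptome differed broadly between the mimics. With the miR-375 mimic 4278 genes were higher and 4271 lower among the 15551 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The series has no untreated or mock-treated libraries, so a difference may come from either mimic. Values are scaled per library, so a shift common to most genes would not show. Most changes were small: the median absolute log2 fold change of the 8549 called genes was 0.37. By at least 1 on the log2 scale 370 genes rose and 233 fell (213 and 157 with a pseudocount of 10). The groups did not overlap at all for 6402 of the called genes, where chance gives 0.794% of genes tested. The first principal component, with 78.3% of the variance over 11468 genes, separated the groups. In the authors' deposited table, a total of 8544 genes passed the same threshold, of which 8428 were also called here, all in the same direction.

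KLF5, a zinc-finger transcription factor of proliferating vascular and epithelial cells and the target named in the series title, did not pass the test. Its level was 94.5 ± 25.5 normalized counts with the NS mimic and 71.2 ± 13.3 with the miR-375 mimic, a log2 fold change of -0.38 (SE 0.18, adjusted p = 0.080 by limma). The 95% confidence interval ran from -0.76 to -0.0050, and an exact two-sided permutation test over all 252 relabellings of the 10 libraries gave p = 0.11. The authors' deposited table gives KLF5 a log2 fold change of -0.42 with an adjusted p of 0.054. Only RNA was analysed here, so these values do not show whether KLF5 protein changed. KLF5 passed only with certain single libraries left out. Without NS mimic replicate 5 the log2 fold change was -0.51 (adjusted p = 0.022) and without miR-375 mimic replicate 3 it was -0.46 (adjusted p = 0.045). Without NS mimic replicate 3 it was -0.25 (adjusted p = 0.25). KLF5 (ENSG00000102554) lies on the plus strand of chromosome 13, from 73054976 to 73077542 (GRCh38). Its annotated 3' UTR of 1656 bases holds 1 match to the miR-375 seed, the 7-base word GAACAAA at 73076368 to 73076374 (bases 482 to 488 of the UTR).

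Other Krüppel-like factors changed more clearly. KLF2, a transcription factor induced by laminar flow that keeps endothelium quiescent, fell from 1271 ± 107 to 403 ± 37.7 normalized counts (3.15-fold lower, adjusted p = 1.5e-13). KLF4, a related flow-induced factor, fell from 125 ± 15.6 to 71.7 ± 9.29 (log2 fold change -0.79, adjusted p = 4.0e-05). KLF15, KLF9 and KLF12 also fell, with log2 fold changes of -0.92, -0.46 and -0.20. KLF13, KLF11, KLF10, KLF7, KLF8 and KLF6 rose, by 0.42, 0.38, 0.27, 0.20, 1.38 and 0.10 on the log2 scale. The KLF8 call was lost in the count tests on 9 libraries (log2 fold changes of 0.91 to 0.95, adjusted p of 0.071 to 0.075), and with a pseudocount of 10 its value was 0.82. The KLF6 call was lost without any of 5 single libraries, NS mimic replicates 2, 4 and 5 and miR-375 mimic replicates 3 and 5 (adjusted p of 0.062 to 0.088). KLF16 and KLF3 had log2 fold changes of -0.08 and -0.11 and were not called, though without miR-375 mimic replicate 5 KLF3 was -0.17 (adjusted p = 0.0094) and without miR-375 mimic replicate 1 it was -0.06 (adjusted p = 0.39). As a list of 14 measured members (6 higher and 5 lower, the same counts when adjusted over the list alone), the family showed no common direction (camera adjusted p = 0.73). A seed match of 7 bases lies in the annotated 3' UTR of KLF4, on the minus strand of chromosome 9 at 107485025 to 107485031, but no match of 6 bases or more lies in that of KLF2. Matches of 7 bases also lie in the UTRs of KLF12 (1), which fell, and KLF3 (2), which was not called. The UTRs of KLF8 (3) and KLF7 (2), which rose, hold them too, so a match did not go with a fall across the family.

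**Figure D1:**
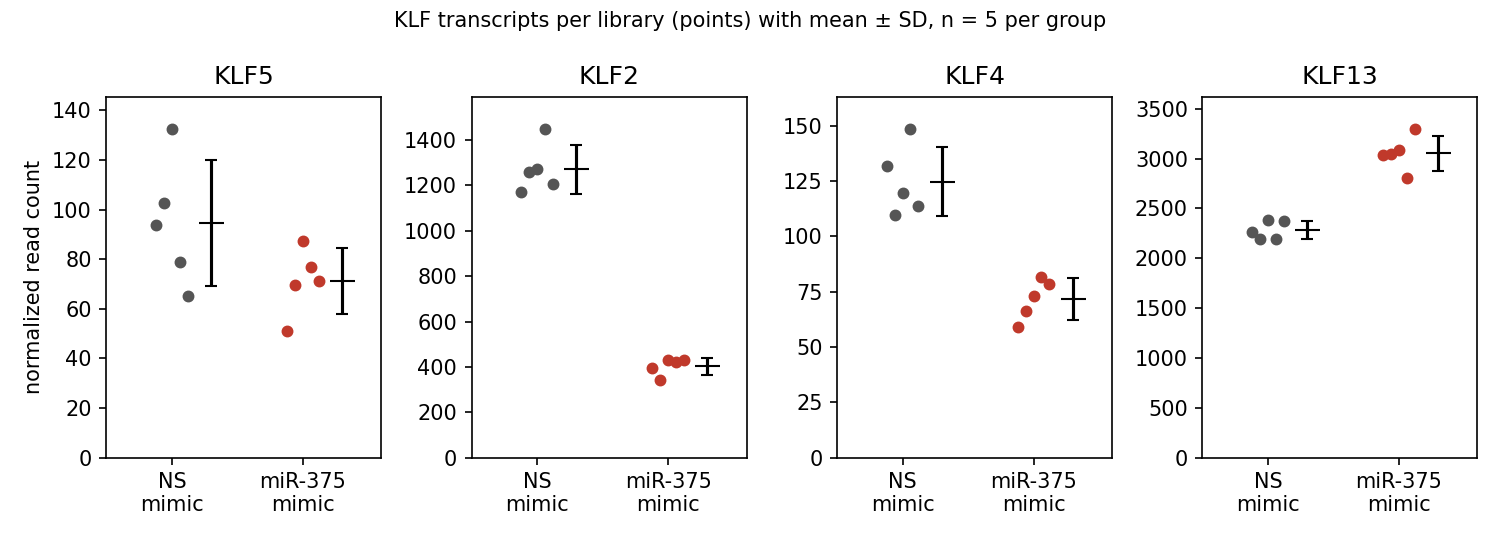
Normalized read counts of KLF5, KLF2, KLF4 and KLF13 in each library (points; grey, NS mimic; red, miR-375 mimic), with the mean and SD of 5 libraries per group beside them, on linear axes that start at 0. The KLF5 groups overlap around means of 94.5 and 71.2, whereas the KLF2 groups lie apart at 1271 and 403.

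Transcripts named in earlier work as miR-375 targets fell as a group. Of 35 measured members of the list, 25 fell and 5 rose (26 and 5 when adjusted over the list alone), with a median log2 fold change of -0.45 (camera adjusted p = 2.8e-08; adjusted p = 0.037 with an estimated correlation). QKI, an RNA-binding splicing regulator, fell from 7861 ± 355 to 2507 ± 180 normalized counts (3.14-fold lower, adjusted p = 3.1e-16). LDHB, a subunit of lactate dehydrogenase, fell from 41992 ± 1010 to 14177 ± 886 (2.97-fold lower). MTDH, an oncogene product also called AEG-1, fell 2.85-fold, and SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, fell 2.28-fold. These 4 had the smallest adjusted p of the list, and all 4 hold a seed match in the annotated 3' UTR. The share of all 35 members with a match was not counted here. MTDH has an 8-base match, CGAACAAA, at 97726124 to 97726131 of chromosome 8 (plus strand), and LDHB has GAACAAA at 21635364 to 21635370 of chromosome 12 (minus strand). SEC23A has the same word at 39033045 to 39033051 of chromosome 14 (minus strand). The QKI UTR of 7886 bases holds 4 copies, the first at 163571623 to 163571629 of chromosome 6 (plus strand).

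Across all genes, those with a miR-375 seed match in the 3' UTR had lower fold changes than those without. The median log2 fold change was -0.12 over 2297 genes with a match of 7 or 8 bases (to nucleotides 2 to 8 of the microRNA, or to nucleotides 2 to 7 followed by an A), and 0.018 over 8672 genes with no 6-base match. The difference was -0.13 (95% bootstrap interval -0.16 to -0.11; two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give). The shift was larger for 60 genes with the 8-base match (-0.28) than for 2091 genes with only the 6-base match (-0.05); that contrast itself was not tested. An 8-base match was counted here as 2 matches of 7 bases. On that count, genes with 1, 2 and at least 3 matches had medians of -0.09, -0.18 and -0.21, over 1767, 397 and 133 genes. The trend therefore mixes the number of matches with their class, and UTR length was not matched. Of the 16265 words of 7 bases found in at least 50 UTRs, CGAACAA had the lowest difference of medians and GAACAAA ranked 3; by a z score, which adjusts for UTR length and expression but also grows with the number of UTRs, GAACAAA (2221 UTRs) ranked 1 and CGAACAA (156 UTRs) ranked 320. Genes are not independent replicates. Of the 2141 genes with the GAACAAA match alone 42.4% were called lower and 22.7% higher, against 27.2% and 32.5% of genes with no match; 3.22% and 1.12% were called lower by at least 2-fold. Among genes named below, matches of 7 bases also lie in the UTRs of NCAPG (1), TYMS (1), ELOVL6 (3) and SLC7A11 (2), which fell. They lie too in those of AGO4 (1), PCDHB5 (1) and PCDHA10 (2), which rose.

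**Figure D2:**
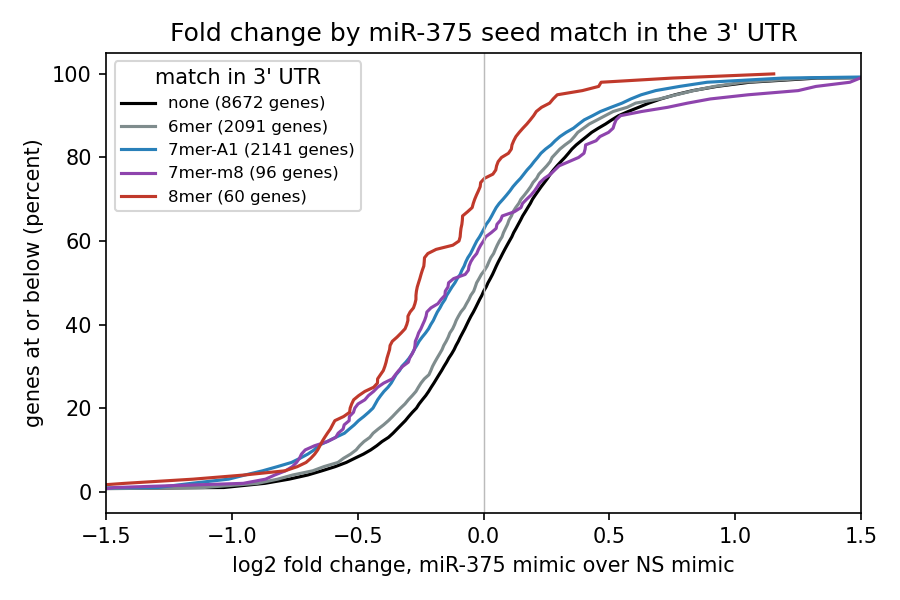
Percentage of genes (vertical axis) at or below each log2 fold change of miR-375 mimic over NS mimic (horizontal axis, shown from -1.5 to 1.5), with one line per class of seed match in the annotated 3' UTR. The line of the 60 genes with an 8-base match lies to the left of the line of the 8672 genes without a match, with medians of -0.26 and 0.018.

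Most cell cycle transcripts fell. All 31 measured genes of the mitosis list fell, with a median log2 fold change of -0.89, and so did 30 of 32 genes of DNA replication, with a median of -0.69, while 1 rose (31 lower for mitosis, and 30 lower and 1 higher for replication, when adjusted over the list alone). KIF20A, a kinesin of the dividing cell's midzone, fell from 3896 ± 75.1 to 1799 ± 108 normalized counts (adjusted p = 2.6e-14), and ANLN, a scaffold protein of the cleavage furrow, and NCAPG, a condensin subunit, fell 2.29-fold and 1.87-fold. TYMS, which makes the thymidylate needed for DNA synthesis, fell from 8021 ± 163 to 3157 ± 242 (2.55-fold lower), and the replicative helicase subunits MCM7 and MCM5 fell 1.82-fold and 1.83-fold. The camera adjusted p was 1.0e-20 for mitosis and 1.4e-16 for replication; for each list the adjusted p was 0.17 with an estimated correlation, since members vary together across libraries. Targets of p53 moved the other way. In that list 18 of 25 measured members rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.17 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 15103 ± 196 to 25748 ± 1167 normalized counts, and the secreted stress cytokine GDF15 rose from 9134 ± 237 to 19277 ± 552. TP53I3, an oxidoreductase induced by p53, rose 1.77-fold.

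Cholesterol and lipid synthesis genes fell. Of 30 measured members 25 fell and 0 rose, also when adjusted over the list alone (median log2 fold change -0.30; camera adjusted p = 1.5e-08; adjusted p = 0.037 with an estimated correlation). ELOVL6, a fatty acid elongase, fell from 1489 ± 49.8 to 618 ± 77.2 normalized counts. EBP, a sterol isomerase, fell by 0.68 on the log2 scale, and the desaturase FADS1 fell by 0.40.

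Genes of the mesenchymal and TGF-beta list rose on balance, with 16 of 27 measured members higher and 4 lower, also when adjusted over the list alone (median log2 fold change 0.32; camera adjusted p = 0.0011; adjusted p = 0.17 with an estimated correlation). TAGLN, an actin-binding protein of smooth muscle, rose from 376 ± 26.7 to 1217 ± 87.2 normalized counts (3.24-fold). The cell adhesion protein CDH2 (N-cadherin) rose 1.84-fold and the receptor kinase TGFBR1 rose 1.90-fold. In the list of extracellular matrix, proteases and integrins, 25 of 38 members rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.00039; adjusted p = 0.62 with an estimated correlation). MMP10, a secreted metalloproteinase, rose 2.68-fold and the urokinase receptor PLAUR rose 1.65-fold, whereas the integrin subunits ITGB4 and ITGA6, which bind laminin as a pair, had log2 fold changes of -2.58 and -0.68.

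**Figure D3:**
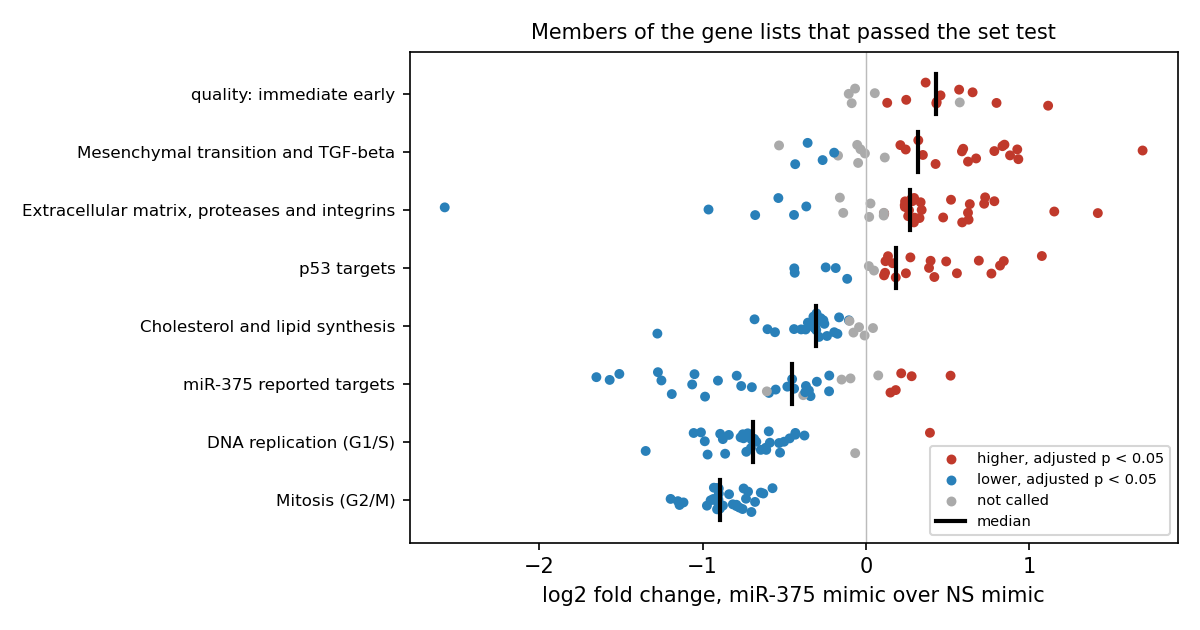
Log2 fold changes of miR-375 mimic over NS mimic (horizontal axis) of each measured member of the 8 gene lists that passed the set test with a preset correlation (one row per list; points, genes; black bars, list medians; red and blue, genes called higher and lower; grey, not called). Median values run from -0.89 for mitosis to 0.43 for immediate early genes.

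Genes of angiogenic signalling moved in both directions. Of 36 measured members 15 rose and 13 fell, also when adjusted over the list alone, with no common direction (camera adjusted p = 0.57). KDR, the main VEGF receptor of endothelium, fell from 10666 ± 420 to 5011 ± 411 normalized counts (2.13-fold lower, adjusted p = 1.7e-13), and its 3' UTR holds GAACAAA at 55079648 to 55079654 of chromosome 4 (minus strand). ANGPT2, a ligand of the TEK receptor that destabilizes vessels, rose from 2286 ± 72.0 to 4970 ± 341. ANGPTL4, a secreted regulator of lipoprotein lipase, rose 3.13-fold, and MET, the receptor of hepatocyte growth factor, rose 2.33-fold. In the Notch list 9 of 18 members rose and 5 fell, 10 and 5 when adjusted over the list alone (camera adjusted p = 0.34). The Notch ligand JAG1 rose 2.21-fold, while LFNG, a glycosyltransferase that modifies Notch, and RBPJ, the DNA-binding partner of Notch, fell 2.00-fold and 1.57-fold. The UTR of RBPJ holds 3 matches of 7 bases, and those of JAG1 and LFNG hold none.

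Endothelial identity genes were not shifted as a list, with 7 of 30 members higher and 13 lower, also when adjusted over the list alone (camera adjusted p = 0.34). Single members changed strongly. BMX, a tyrosine kinase of endothelium, fell from 5310 ± 84.9 to 1919 ± 62.5 normalized counts, VWF, the clotting glycoprotein, fell from 43969 ± 2548 to 22689 ± 3734, and CD34 fell 2.43-fold. ENG (endoglin, a TGF-beta co-receptor) rose by 0.68 on the log2 scale. Of 21 flow-responsive and anticoagulant genes 12 fell and 7 rose, also when adjusted over the list alone (camera adjusted p = 0.20). NOS3, the endothelial nitric oxide synthase, fell from 4864 ± 271 to 2126 ± 113, NQO1, a quinone reductase, fell 2.27-fold, and the heme oxygenase HMOX1 fell 1.56-fold. Of 26 genes of the NF-kB and adhesion list 6 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.35). The neutrophil chemokine CXCL8 rose from 430 ± 44.6 to 2068 ± 146, whereas the monocyte chemokine CCL2 fell 3.12-fold and the leukocyte adhesion receptor ICAM1 fell 2.56-fold.

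The genes with the largest changes whose groups did not overlap were mostly of low level. With the pseudocount of 1, the 10 largest decreases were of CYP1A1, KIF19, TSPAN8, AQP1, ITGB4, DEPP1, TNFSF10, HTR2B, L3HYPDH and CHRNA1, with log2 fold changes from -3.49 to -2.25. CYP1A1, a xenobiotic-metabolizing enzyme, fell from 173 ± 25.9 to 15.9 ± 8.23 normalized counts (adjusted p = 3.6e-10), and it alone of the 10 had a 7-base seed match in its 3' UTR. DEPP1, a target of FOXO factors, fell from 1411 ± 168 to 255 ± 33.2, and TNFSF10, the death ligand TRAIL, fell from 162 ± 17.5 to 30.0 ± 9.86. The 10 largest increases, with the same pseudocount, were of SHH, GCNT4, FLG-AS1, IL11, CD69, PCDHB2, TPBG, NAP1L2, NRK and CXCL8, with log2 fold changes from 3.35 to 2.27, and 0 of the 9 with an annotated 3' UTR had a 7-base match (FLG-AS1 has none to search). Over all genes with an annotated 3' UTR 17.6% hold a match of 7 or 8 bases, so counts among so few genes tell little. SHH, the hedgehog ligand, rose from 4.07 ± 2.37 to 47.6 ± 9.63, the cytokine IL11 rose from 5.02 ± 2.14 to 42.8 ± 3.80, and TPBG, a surface glycoprotein, rose from 187 ± 18.1 to 990 ± 89.1. The order and membership of both groups depend on the pseudocount. With a pseudocount of 10, KIF19, AQP1 and CHRNA1 had log2 fold changes of -1.68, -1.73 and -1.35, and KLF2, not among the 10, then fell more than CHRNA1. SHH, GCNT4, IL11, CD69 and FLG-AS1 then had values from 2.03 down to 1.46 in this order, and RELN, not among the 10, had 1.91. FLG-AS1 is annotated as antisense, and the strand used in counting is not given in the sources used here, so its reads cannot be told from those of genes on the other strand.

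Markers of other cell types did not move together. Of 7 measured smooth muscle and pericyte markers 2 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.73), and ACTA2, a smooth muscle actin that the mesenchymal list also holds, rose from 427 ± 17.8 to 816 ± 41.7 normalized counts. Of 10 fibroblast markers 3 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.69), among them COL3A1, a fibrillar collagen, which rose 1.58-fold. For both lists the median and the test differed in sign. Of 7 epithelial markers 1 rose and 4 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.34), with KRT8 falling 1.94-fold and KRT18 1.37-fold. Of 7 lymphatic markers 4 rose and 2 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.34): RELN rose 3.93-fold and PROX1 1.70-fold, while LYVE1 fell 1.93-fold. Only 3 leukocyte markers (2 higher and 0 lower; 2 and 1 when adjusted over the list alone) and 1 erythroid marker (not called, but 1 lower when adjusted over the list alone) were measured, too few for the set test. Immediate early genes, listed as a sign of handling stress, rose: 10 of 15 members were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.27 with an estimated correlation). EGR1 rose 1.74-fold and DUSP1 1.35-fold. The call of that list was lost with DESeq2 on 9 libraries (adjusted p = 0.12) and with the authors' deposited table (adjusted p = 0.097). Of 13 mitochondrially encoded genes 0 rose and 4 fell (0 and 3 when adjusted over the list alone; camera adjusted p = 0.34), and of 25 ribosomal protein genes 3 rose and 1 fell (0 and 0 when adjusted over the list alone; camera adjusted p = 0.79; median -0.01, mean 0.01).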

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

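The seed match test and the count over other splits were planned before the data were examined; the composition, cell cycle and depth tests were chosen after the results were seen. A library was singled out where it lay far from the other 4 of its group (gap over range above Dixon's 95% critical value for 5 libraries). This happened in 8 of 200 groups, where chance gives about 5%. In miR-375 mimic replicate 1, ANGPTL4 was low at 2729 normalized counts against 3013 to 3092 in the others, and ITGB4 was low at 60.9 against 80.3 to 88.0. The same library was high for IFI27, at 2185 against 1787 to 1876, and for PCDHB2, at 87.8 against 48.1 to 56.5. NS mimic replicate 5 was low for DUSP1, at 1396 against 1578 to 1603, and high for CD69, at 10.2 against 1.58 to 3.48. In NS mimic replicate 3 PCDHB14 was low at 25.4 against 33.1 to 35.7, and in miR-375 mimic replicate 4 NAP1L2 was high at 92.8 against 50.3 to 62.3.

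The number of called genes was compared with that of other splits of the libraries. Of 100 splits of the 10 libraries into 5 and 5, drawn from 126, only 1 (the real one, with 8549 genes by limma) gave as many, and the highest of the others gave 0. Each of the other splits mixes the groups and so adds their difference to the residual spread, which holds down its calls. The count cannot tell the mimic from a difference of culture or handling between the groups.

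Genes with a miR-375 seed match had lower fold changes than genes without (difference of medians -0.13). A candidate explanation is direct repression through the matches, and this is a hypothesis. The planned test asked for a shift below 0 and a rank of the 7-base word in the lowest 1% of words; the planned word CGAACAA (156 UTRs) met it by difference of medians (rank 1 of 16265) but not by a z score of the mean after adjustment for UTR length and expression (rank 320), while GAACAAA (2221 UTRs) ranked 3 and 1; the z score also grows with the number of UTRs. Base composition, UTR length and expression together are argued against as the whole cause: with controls matched on all of these, the difference was -0.15 (permutation SD 0.017). By the z score GAACAAA also ranked first of the 42 words made of the same letters. That place was fixed by its rank of 1 among all words, so it is no separate evidence. Matches in coding sequence went with a similar shift, -0.16, in genes without a UTR match, and coding length was not matched there.

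Cell cycle genes fell with miR-375, and 5 of the 63 (7.94%) hold a 7-base or 8-base match in the 3' UTR against 17.6% of all genes. Direct matches are argued against as the whole cause, since the 20 members with no match of 6 bases in UTR or coding sequence had a median of -0.70 (SD over genes 0.16) and all 20 were called lower. A trend with composition, length and expression is argued against as well, since the median was -0.74 after subtracting matched genes. Lower depth is argued against for these pairs only: in the 4 pairs where the miR-375 mimic library (replicate 2 or 3) was the deeper one, the median difference over the 63 genes ran from -0.82 to -0.73 (SD over genes 0.26 to 0.32). Replicate 2 had 47.4 M reads against 36.3 M to 46.3 M, and replicate 3 had 38.3 M against 36.3 M. Some pairs thus differ little in depth, the pairs share libraries, and the genes vary together. Indirect effects of the mimic and culture density stay open and were not tested.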

How the results depend on the processing

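Alternatives with other scaling factors, count tests on 9 libraries and the deposited comparison were chosen after seeing the data, as was matching on GC content; the others were planned. The count of 8549 called genes stayed between 8059 and 8581 under every alternative that kept the threshold, and 6985 genes were called at adjusted p under 0.01. With an absolute log2 fold change of at least 1 added, 603 genes were called, 370 higher and 233 lower. That count depended on the pseudocount: with 10 it was 370 genes, 213 higher and 157 lower. Without a filter on low values no gene is added, so that setting was void. Analyses listed beforehand for raw counts of all 10 libraries, or for a table with only the authors' comparison, were not run since the table holds normalized values. The replicate block gave 8470 genes. Little sign was seen that the numbers pair the libraries: same-numbered libraries correlated at -0.02, -0.02, 0.30, -0.12 and -0.20, and 1 of 10 libraries correlated best with its own number. A shared culture or day cannot be excluded from so few values. With the block no call of a named gene or of a list changed.

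The 8 list calls fell to 2 with an estimated correlation, and 23 lists were called with fry, which does not compare a list with other genes. Flow-responsive genes were called with DESeq2 (adjusted p = 0.00812) and with the deposited table (adjusted p = 0.011), and autophagy and lysosome genes likewise (0.039 and 0.038); the cause was not tested. KLF5 ranged from -0.51 to -0.25 over the libraries left out and was called in 2 of the 10, and the cause was not tested. Of 95 called genes named, 92 were called under all 21 alternatives; KLF8, KLF6 and MT-ND1 lost the call in some, and 0 reversed. The seed shift stayed below 0 in all 29 alternatives, from -0.28 to -0.05. These ends belong to other site classes, the 8-base match alone and the 6-base match alone. With single libraries left out the shift ran from -0.15 to -0.12, and with edgeR on 9 libraries it was -0.12. KLF5 had 59 to 167 reads in each of 9 libraries. Of simulated genes at a similar level given its fold change, 50.4% were called. The fold change planted was the KLF5 estimate itself, which lies near the threshold. That share therefore largely restates its p-value and is no separate evidence that a true change was missed. Depth and spread between libraries were not tested apart.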

Other observations

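The clustered protocadherins, neural cell adhesion proteins encoded in tandem on chromosome 5, form a list chosen after the values were seen. Of 36 measured genes 23 rose and 1 fell (median log2 fold change 0.70; camera p = 8.4e-05, and p = 0.037 with an estimated correlation, neither adjusted for the choice). Of 13 genes of the beta cluster 9 rose and 0 fell. PCDHB2 rose from 8.18 ± 1.33 to 60.1 ± 15.8 normalized counts, PCDHB5 from 13.1 ± 5.95 to 52.3 ± 5.34, PCDHB14 from 32.5 ± 4.10 to 91.6 ± 15.7 and PCDHA10 from 11.1 ± 1.96 to 50.4 ± 14.4. These genes are close copies, and those of the alpha and gamma clusters share exons, so the split of reads among them is uncertain.

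Several metabolic and stress lists that were not called held strong single changes. Of 27 genes of unfolded protein and amino acid stress 9 rose and 13 fell (camera adjusted p = 0.34). The serine synthesis enzymes PSAT1 and PHGDH fell 2.31-fold and 1.68-fold, and the cystine transporter SLC7A11, also on the list of reported targets, fell from 8537 ± 279 to 3544 ± 350 normalized counts. Of 31 glycolysis and hypoxia genes 9 rose and 9 fell (camera adjusted p = 0.66; median and test differ in sign), with the glucose transporter SLC2A3 2.13-fold higher and the collagen prolyl hydroxylase P4HA2 1.70-fold higher. Of 27 autophagy and lysosome genes 16 rose and 8 fell (camera adjusted p = 0.064, but called higher with DESeq2 on 9 libraries, adjusted p = 0.039, and with the authors' deposited table, adjusted p = 0.038), among them GABARAP at 1.41-fold and ULK1 at 1.70-fold. Of 30 nuclear genes of oxidative phosphorylation 7 rose and 9 fell (8 and 9 when adjusted over the list alone; camera adjusted p = 0.57). Of 15 small-RNA pathway genes 5 rose and 9 fell (camera adjusted p = 0.34), with AGO4 1.38-fold higher and DROSHA 1.21-fold lower. Of 33 interferon response genes 13 rose and 6 fell (camera adjusted p = 0.34), with IFI27 and IFIT5 both 1.62-fold higher. Of 25 YAP/TEAD targets 12 rose and 6 fell (camera adjusted p = 0.34), and ANKRD1 and TGFB2 rose 1.75-fold and 1.80-fold. Of the mitochondrially encoded genes, MT-ND1 fell from 11054 ± 2292 to 8644 ± 1401, a call lost with DESeq2 on 9 libraries (adjusted p = 0.083) and in the authors' deposited table (adjusted p = 0.065).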
